A study of Mus musculus with 3 samples.

How the data were processed

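ChIP-seq libraries were made from splenic B220+ B cells of mice with the MD4 transgene, isolated with magnetic beads and stimulated with anti-CD40, IL-21 and HEL. Per the labels' protocols, lysates were prepared with the EZ-ChIP kit and sonicated, and sequencing libraries followed Illumina's instructions. The labels describe 3 libraries, which differ in the antibody: anti-Jmjd2a, anti-Jmjd2c and normal rabbit IgG. The last is titled as an input, and a peak list for it was not analysed here.

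Per the submitters' processing notes, FastQC and Bowtie 0.12.7 were used and the genome build was mm9. The peak names in the files carry the prefix of MACS, a model-based peak caller; its version, settings and use of the IgG library are not given in the sources used here. The authors deposited 1 peak list per ChIP library, so peaks were called per library and not on pooled reads. Each deposited line holds a chromosome, a start, an end, a name and a score. The deposited score is the authors' own value per peak and no header names its scale. It starts at 50.01 in both lists and has a ceiling of 3100. It was used only to rank, split and describe peaks within a list. How strongly a region was covered, and how the libraries compared in depth, cannot be read from these values, so the depth is unknown.

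Peaks were compared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Overlap meant at least 1 bp in common. Chance overlap came from 1000 random placements of the Jmjd2c peaks within their own chromosome, from its first base to the last peak end of either list, since no mm9 genome was used here. The same extents gave the expected peaks per chromosome for exact binomial tests over 21 chromosomes in both lists. Unmappable sequence was not excluded from placements or extents. Median widths were compared by 100000 permutations of the list labels, scores of overlapping pairs by Spearman's rho with 100000 permutations, and shares of peaks in blocks by Fisher's exact test. Benjamini-Hochberg adjustment used a threshold of 0.05. It ran over both lists and all settings for the overlap and clustering tests, over all settings for the width test and the score relation, over the chromosomes of both lists within a setting for the chromosome test, and over the 6 blocks for Fisher's test. Intervals for shares are 95% Wilson intervals and cover counting error only. Coordinates were converted to count from 1.

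The overlap test, the chromosome test, the width test, the score relation, the clustering test and their main alternatives were fixed before the data were examined. The alternatives were a 50% reciprocal overlap, centres within 1 or 5 kb, the peaks of each list at or above its median score, merging of peaks closer than 1 kb, leaving out chromosome Y, placement over the whole genome, and clustering distances of 1 and 100 kb. For widths, leaving out peaks that overlap the other list was a further alternative fixed beforehand. Dense blocks and all settings that use them, the restriction to autosomes and the peaks moved at random were chosen after the data were examined. A block is a set of at least 20 peaks of both lists in which no gap exceeds 500 kb. Peaks named in the text were to be the 10 with the highest score per list and the 10 shared pairs with the best sum of ranks; ties at the ceiling made the first set 15 in the Jmjd2a list. Autosomal peaks were added afterwards because this rule named chromosome Y alone.

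Planned results that need genes were not run: genes common to both lists, peaks near transcription starts, shares of exons, introns and promoters, the gene lists and single genes fixed beforehand, and placements matched to transcription starts. The gene table at hand is of GRCm38, and its coordinates cannot be used with mm9 peaks.

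The overlap, chromosome, width, score relation, clustering and repeated-distance tests were tried on simulated data, made from the real peaks' widths, scores or positions except for invented clusters in the last; Fisher's test, the score-matched draws and the score comparison of shared and one-library peaks were not. With 200 shared peaks planted, 200 Jmjd2a peaks were found shared. Of 100 unrelated pairs of lists, 1 passed the overlap threshold. Random lists gave 0 of 42 chromosome tests past the threshold. These lists were placed uniformly at random, as the tests assume, so the rates were not checked for unrelated lists that cluster in the same stretches.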

Results

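The series asked where Jmjd2a and Jmjd2c, a pair of JmjC histone H3 lysine demethylases, bind the genome of mouse B cells that receive signals of the kind T follicular helper cells give. Splenic B220+ B cells of C57BL/6 mice carrying the MD4 immunoglobulin transgene, whose B cell receptor recognises hen egg lysozyme, were stimulated with anti-CD40, IL-21 and HEL, the label's name for that antigen. Chromatin was then immunoprecipitated with an antibody against Jmjd2a, an antibody against Jmjd2c or normal rabbit IgG, with 1 library for each of the 3. A peak list was analysed for each demethylase. The Jmjd2a list held 1139 peaks that covered 330.6 kb, and the Jmjd2c list held 1113 peaks that covered 289.3 kb. Peak scores started at 50.01 in both lists and stopped at 3100, a value reached by 15 Jmjd2a and 9 Jmjd2c peaks. The lists give no read numbers, so the sequencing depth behind a peak is unknown. With 1 library per antibody no difference has a replicate check. The tests below treat peaks as units, which are not replicates, and describe these 2 lists alone. Positions are in mm9, the build in the submitters' processing notes, and are counted from 1. No mm9 gene annotation was used here, so peaks are named by position and not by gene.

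The first question was where in the genome the peaks lay. Both lists held far more peaks on the sex chromosomes than the extent of these chromosomes would give. Chromosome X held 481 of the 1139 Jmjd2a peaks (42.2%) and 338 of the 1113 Jmjd2c peaks (30.4%), which was 6.55 and 4.71 times the number expected from the chromosome's extent. Chromosome Y held 134 Jmjd2a peaks (11.8%) and 150 Jmjd2c peaks (13.5%), within a stretch that the extent would give 1.28 and 1.25 peaks. Each extent ended at the last peak of either list, at 2902507 on Y. The Y expectation and the p-values built on it thus depend on where the peaks stop. Only 46.0% of Jmjd2a peaks and 56.2% of Jmjd2c peaks were autosomal. In exact two-sided binomial tests, the excess on X had an adjusted p of 1.2e-255 for Jmjd2a and 2.2e-129 for Jmjd2c. The excess on Y had an adjusted p of 1.3e-217 for Jmjd2a and 1.1e-252 for Jmjd2c. Crowded peaks are not independent draws, so these p-values overstate the evidence. With peaks closer than 1 kb merged, X stood at 4.81 times expectation for Jmjd2a (exact binomial test, adjusted p = 1.6e-85). For Jmjd2c it stood at 3.42 times (exact binomial test, adjusted p = 3.4e-40). Most autosomes were low in return, and 18 of them in the Jmjd2a list and 16 in the Jmjd2c list passed the adjusted threshold below expectation. Chromosome 5 in the Jmjd2c list was the exception, with 76 peaks, 1.18 times expectation (exact binomial test, adjusted p = 0.14). It passed as an excess when peaks closer than 1 kb were merged, at 1.47 times expectation (exact binomial test, adjusted p = 0.015). The same merging cut the chromosomes past the threshold from 20 to 10 for Jmjd2a and from 18 to 8 for Jmjd2c. Much of chromosome X's count came from a few stretches. Once 6 dense blocks of peaks, described next, were left out, chromosome X stood at 1.41 times expectation in the Jmjd2a list (exact binomial test, adjusted p = 0.39) and 0.90 times in the Jmjd2c list (adjusted p = 0.85), and 0 of the 21 chromosomes passed in either list, with 2 in each at an unadjusted p under 0.05, X in the Jmjd2a list among them (p = 0.021). The blocks were picked as the densest stretches, so leaving them out lowers these ratios by construction.

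**Figure D1:**
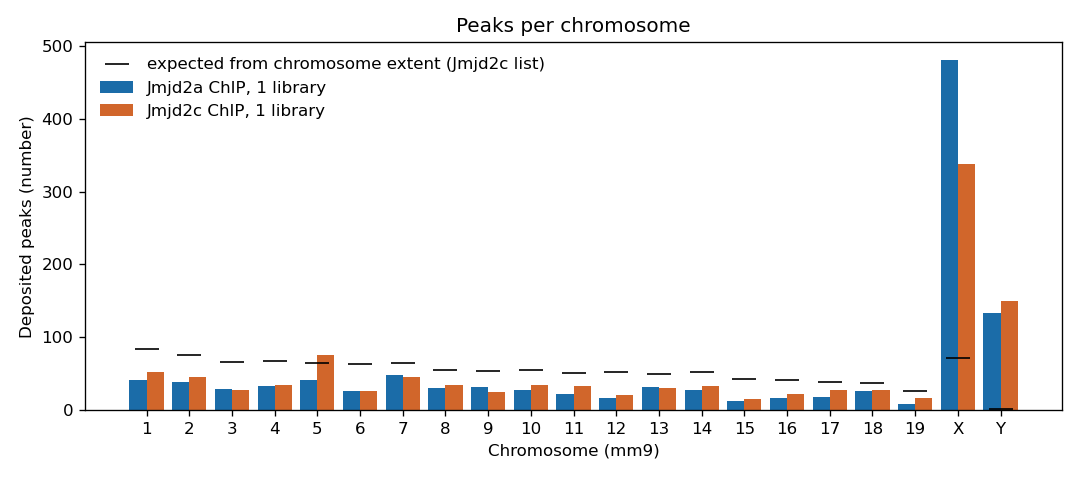
Number of deposited peaks on each chromosome in the Jmjd2a library (blue) and the Jmjd2c library (orange), 1 library each; black marks show the number expected from chromosome extent for a list of the Jmjd2c list's length. Chromosome X, with 481 and 338 peaks, and chromosome Y, with 134 and 150 peaks, stand above the marks.

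The dense blocks held about the same number of peaks as the rest of the genome: 609 Jmjd2a peaks (53.5%) and 527 Jmjd2c peaks (47.3%). A block was a group of at least 20 peaks of both lists together with gaps of at most 500 kb, a rule set after the lists were examined. The largest lay on chromosome X from 120071579 to 122848513 and held 409 Jmjd2a peaks and 293 Jmjd2c peaks. The block on chromosome Y ran from 1263417 to 2902507 and held every Y peak of both lists. Its scores were high, with a median of 204.5 for Jmjd2a and 220.4 for Jmjd2c. A second X block, from 52956741 to 53525101, held 24 Jmjd2a and 11 Jmjd2c peaks. The autosomal blocks were on chromosome 7 from 71228773 to 71640639, with 26 Jmjd2a and 27 Jmjd2c peaks, on chromosome 2 from 27333045 to 27358218, with 15 and 16 peaks, and on chromosome 5 from 14928447 to 15198919.

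**Figure D2:**
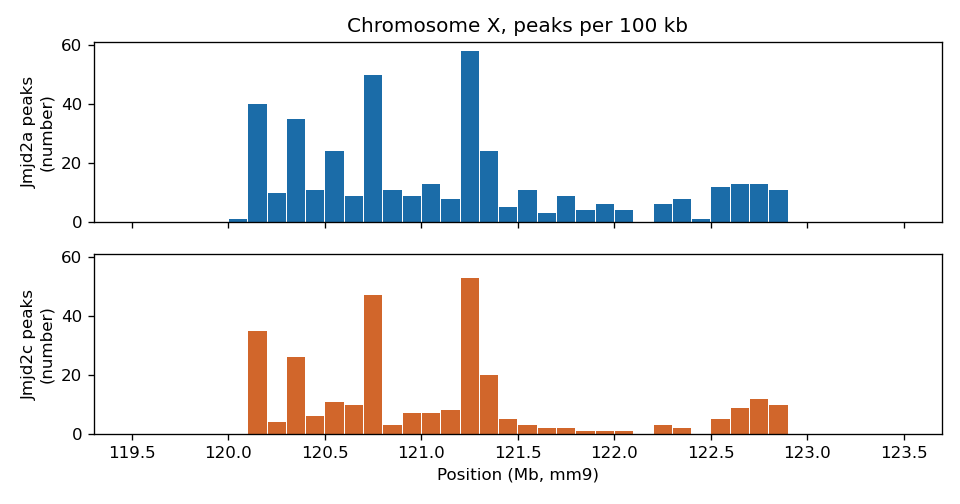
Number of peaks per 100 kb along chromosome X between 119.5 and 123.5 Mb (mm9) in the Jmjd2a list (top) and the Jmjd2c list (bottom). The tallest bin starts at 121.2 Mb in both lists, with 58 Jmjd2a and 53 Jmjd2c peaks.

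The next comparison asked which blocks differed between the 2 demethylases. The large X block held a larger part of the Jmjd2a list, 35.9% (95% Wilson interval 33.2 to 38.7), than of the Jmjd2c list, 26.3% (23.8 to 29.0). The odds ratio was 1.57 (Fisher's exact test, two-sided, adjusted p = 3.3e-06 over the 6 blocks), and the covered length was 94.5 kb against 57.0 kb. The chromosome 5 block went the other way. It held 30 Jmjd2c peaks, 2.70% of that list (1.89 to 3.82), and 1 Jmjd2a peak, 0.0878% (0.0155 to 0.496), at an odds ratio of 0.032 (Fisher's exact test, adjusted p = 5.6e-08). The Jmjd2c peaks there scored between 50.91 and 124.66, and the single Jmjd2a peak scored 56.04 and overlapped none of them. The chromosome 5 block met the block rule, and got its limits, through its Jmjd2c peaks alone. A low odds ratio is thus favoured by how the block was chosen, and its Fisher p-value overstates the evidence. Neither adjustment over the 6 blocks nor the merging below corrects for this choice. The Y, chromosome 7 and chromosome 2 blocks did not pass the test, with odds ratios of 0.86, 0.94 and 0.91 and adjusted p of 0.34, 0.89 and 0.89. The smaller X block, at an odds ratio of 2.16, also did not pass (Fisher's exact test, adjusted p = 0.080). Neighbouring peaks of a block are not independent. After peaks closer than 1 kb were merged, the odds ratio was 1.51 for the large X block and 0.046 for the chromosome 5 block. With this merging, the unadjusted p of Fisher's exact test rose from 1.1e-06 to 0.0023 for the large X block. For the chromosome 5 block it rose from 9.4e-09 to 4.9e-06.

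**Figure D3:**
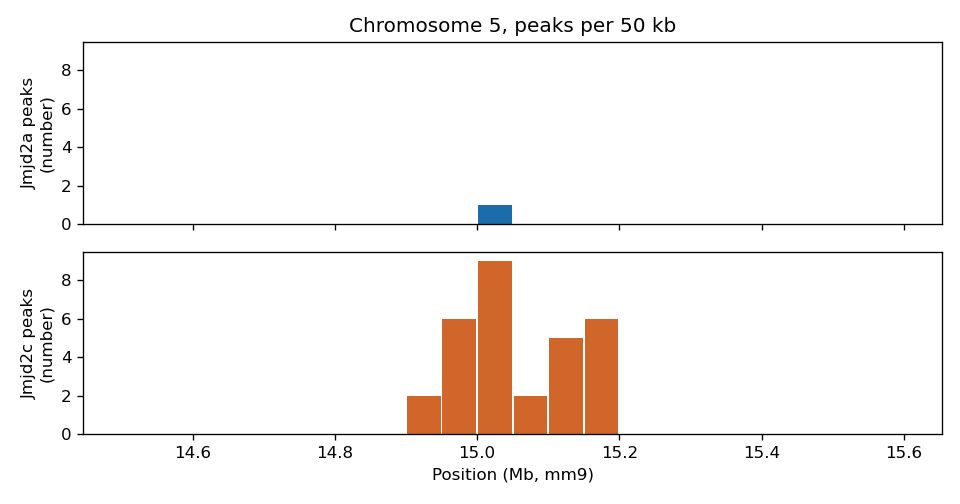
Number of peaks per 50 kb along chromosome 5 between 14.5 and 15.6 Mb (mm9) in the Jmjd2a list (top) and the Jmjd2c list (bottom). The 30 Jmjd2c peaks of the block stand against 1 Jmjd2a peak.

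The central question of the design was how far the peaks of the 2 demethylases lay in the same regions. Overlap of the lists does not separate binding of both proteins from signal that arises with any antibody, since no IgG peak list was analysed. Of the Jmjd2a peaks, 555 of 1139 (48.7%, 45.8 to 51.6) shared at least 1 bp with a Jmjd2c peak, and 623 of 1113 Jmjd2c peaks (56.0%, 53.0 to 58.9) met a Jmjd2a peak. Random placement of the Jmjd2c peaks within their chromosomes gave a mean of 7.55 Jmjd2a peaks and never more than 20 (1000 placements, one-sided permutation p = 0.001, adjusted p = 0.001, the smallest they can give). When each Jmjd2c peak was instead moved at random by up to 10 kb, which keeps the dense stretches in place, a mean of 172.4 Jmjd2a peaks and at most 204 were shared, so that the observed count was 3.22 times this mean against 73.5 times the mean of the placements. On chromosome Y, 98 of 134 Jmjd2a peaks (73.1%) and 140 of 150 Jmjd2c peaks (93.3%) were shared. In the large X block, 227 of 409 Jmjd2a peaks (55.5%) and 242 of 293 Jmjd2c peaks (82.6%) were shared, against a mean of 18.2 Jmjd2a peaks when Jmjd2c peaks were placed at random inside the block. Outside the 6 blocks the shares were lower, at 193 of 530 Jmjd2a peaks (36.4%, 32.4 to 40.6) and 203 of 586 Jmjd2c peaks (34.6%, 30.9 to 38.6). There, moving each Jmjd2c peak at random by up to 10 kb left a mean of 18.0 shared Jmjd2a peaks and at most 33. The observed count was 10.7 times this mean, against 3.22 times for the same move over all peaks. The mean of 18.2 in the X block came from placement anywhere in the block, which does not keep runs of peaks in place. It cannot be set beside the mean of 18.0. The centres of overlapping peaks outside the blocks lay a median of 29 bp apart.

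The regions with the highest scores were common to both lists. All 15 Jmjd2a peaks and all 9 Jmjd2c peaks at the score ceiling were on chromosome Y, and each overlapped a peak of the other list. The 10 shared pairs with the best ranks were also all on Y, between 2779610 and 2889631. Because this rule named Y alone, the leading autosomal regions were added after the values were seen. The first was on chromosome 10, where a Jmjd2a peak from 7232507 to 7235340 scored 2154.81 and a Jmjd2c peak from 7232505 to 7235310 scored 2455.24. It belonged to a group of 7 Jmjd2a and 7 Jmjd2c peaks between 7229367 and 7237176, all of them shared. A region of chromosome 17, from 36621572 to 36621922 in the Jmjd2a list, scored 940.07 for Jmjd2a and 1072.98 for Jmjd2c. A second region of chromosome 17, from 13743505 to 13746139 in the Jmjd2a list, scored 449.45 for Jmjd2a and 913.86 for Jmjd2c. On chromosome 5, separate from the block above, a peak from 105356688 to 105357294 scored 686.78 for Jmjd2a, and its Jmjd2c partner scored 704.91. Compact groups of peaks also lay on chromosome 18 from 7319773 to 7323666, with 7 Jmjd2a and 10 Jmjd2c peaks, all shared, and on chromosome 14 from 45289678 to 45293631, with 7 and 9 peaks, of which 6 and 9 were shared. On chromosome 13, a peak from 4560411 to 4560804 scored 409.28 for Jmjd2a and 441.12 for Jmjd2c. Scores are the authors' own values for each list and are not scaled between libraries. No IgG peak list was analysed, so at these regions binding cannot be told apart from signal that arises with any antibody.

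Outside the blocks, peaks called in 1 library had lower scores than shared peaks. Shared Jmjd2a peaks had a median score of 103.0 and Jmjd2a peaks without a Jmjd2c partner had 61.0. The corresponding medians in the Jmjd2c list were 92.3 and 59.1. In the highest score quartile of the Jmjd2a list 80.5% of peaks (72.9 to 86.3) were shared, against 13.4% (8.67 to 20.2) in the lowest quartile. In the Jmjd2c list these shares were 74.8% (67.2 to 81.2) and 15.2% (10.4 to 21.8). The strongest autosomal Jmjd2a peak without a partner, outside the blocks, was on chromosome 12 from 4219657 to 4221796 and scored 206.55. It was followed by peaks on chromosome 5 from 145175246 to 145175792 (score 177.93) and on chromosome 9 from 115059459 to 115059649 (score 170.00). The strongest such Jmjd2c peaks were on chromosome 6 from 142932210 to 142932523 (score 165.58), chromosome 11 from 55078633 to 55079021 (score 159.75) and chromosome 15 from 98237996 to 98238401 (score 152.92). These peaks too were picked after their values were seen.

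**Figure D4:**
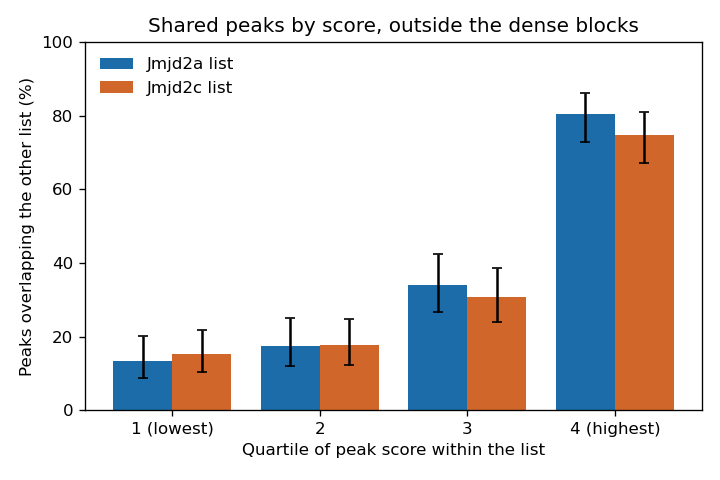
Percentage of peaks that overlapped a peak of the other list, by quartile of peak score within each list, outside the 6 dense blocks; error bars are 95% Wilson intervals and cover counting error only. The share climbs from 13.4% to 80.5% in the Jmjd2a list and from 15.2% to 74.8% in the Jmjd2c list.

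Where the lists overlapped, regions that scored high for Jmjd2a also tended to score high for Jmjd2c. Spearman's rho across the 651 overlapping pairs was 0.66 (permutation p = 1e-05, the smallest 100000 resamples can give, adjusted p = 1e-05). Within the large X block rho was 0.65 over 255 pairs, on chromosome Y it was 0.67 over 146 pairs, and outside the 6 blocks it was 0.43 over 209 pairs, each at the same p. These are correlations across peaks, which are not independent replicates. A peak with several partners entered several pairs, and the permutation treated each pair as a separate unit. The p-values therefore overstate the evidence.

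**Figure D5:**
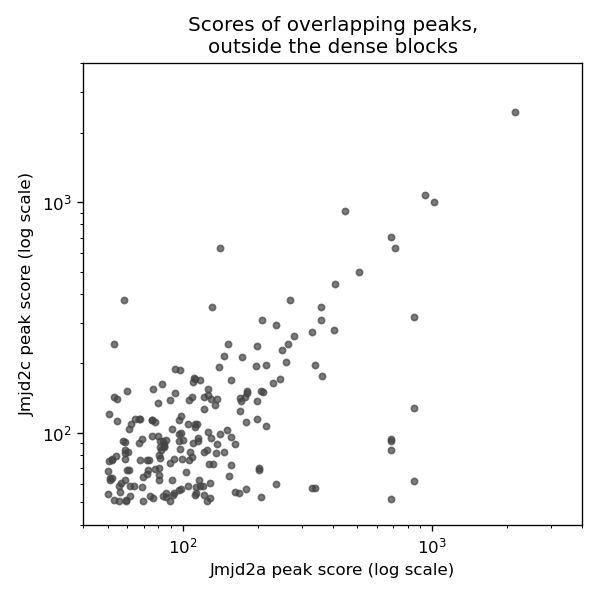
Scores of the 209 overlapping peak pairs outside the 6 dense blocks, Jmjd2a on the horizontal and Jmjd2c on the vertical log axis; each point is 1 pair. Spearman's rho was 0.43, and the pair at the upper right is the chromosome 10 region.

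Jmjd2a peaks were slightly wider, with a median of 197 bp (quartiles 152 and 271) against 178 bp (145 and 241) for Jmjd2c. The difference of 19 bp passed a two-sided permutation test over peaks (p = 1e-05, adjusted p = 4e-05). Among peaks found in 1 list only, the medians were 174.5 and 170 bp and the difference did not pass (permutation test, adjusted p = 0.66). In the Y block the Jmjd2a median was the lower one, 201 against 229 bp, as in the smaller X block, 126 against 141 bp. It was the higher one in the other blocks, with 197 against 163 bp in the large X block. Outside the 6 blocks it was 195 against 177 bp. Widths within single blocks were not tested. Peaks of both lists lay in groups. In the Jmjd2a list 726 peaks (63.7%) had another peak of the same list within 10 kb, against a mean of 109 in random placements, and in the Jmjd2c list 628 peaks (56.4%) did, against 113. Outside the 6 blocks 131 of 530 Jmjd2a peaks (24.7%) and 131 of 586 Jmjd2c peaks (22.4%) did. Random placement gave means of 2.25 and 2.84 peaks there (one-sided permutation p = 0.001 in all 4 cases).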

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

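Of 61 alternative values for 14 results, 52 counted as unchanged. For most results this meant the same direction and the same side of the threshold. For the counts of chromosomes past the threshold it meant a count near the main one. The settings that use dense blocks, autosomes only, the moved peaks, and the block odds ratios with all their settings were chosen after seeing the data. The shared percentage ranged from 36.4 to 73.1 for Jmjd2a and from 34.4 to 93.3 for Jmjd2c and was above random placement under every setting, but the margin depended on the reference: the Jmjd2a count was 73.5 times the mean of placements within chromosomes and 3.22 times that of peaks moved by up to 10 kb. Without the dense blocks, which were picked as the densest stretches and whose length still counts in the expectation, the X ratio to expectation was 1.41 for Jmjd2a and no longer passed (unadjusted p = 0.021 by the exact binomial test), it turned to 0.90 for Jmjd2c, and the Y ratio was 0 in both lists because the Y block holds every Y peak. Chromosomes past the threshold went from 20 to 10 for Jmjd2a and from 18 to 8 for Jmjd2c when peaks closer than 1 kb were merged; the cause was not tested, and the better-scoring part of each list, with fewer peaks, gave 20 and 19. Merging also made chromosome 5 of the Jmjd2c list pass as an excess, at a ratio of 1.47 against 1.18. With the blocks left out 0 passed in either list by the exact binomial test, with 2 in each list at an unadjusted p under 0.05. The width difference was 4.5 bp among peaks found in 1 list only and did not pass; the cause was not tested. Unknown depth limits every statement about peaks missing from a list. No paired analysis was possible because each antibody has 1 library, and for the same reason no replicate could be left out. Results and placements that need transcription starts were not run.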

Other observations

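The tests of copied sequence in the X block and of the score floor were chosen after their results were seen, as were the gap shuffling and the runs of peaks; the other tests were written down first. Runs of at least 5 Jmjd2c peaks with gaps of at most 100 kb numbered 20. Besides the chromosome 5 block, the runs with the lowest sharing were on chromosome 1 from 192124204 to 192127300 and on chromosome 4 from 3007180 to 3017201, each with 1 of 5 Jmjd2c peaks shared. Runs on chromosome 10 from 7229372 to 7237176, on chromosome 14 from 45289678 to 45293627 and on chromosome 18 from 7319794 to 7323646 had all of their 7, 9 and 10 Jmjd2c peaks shared. Outside the 6 blocks, 35 of 337 Jmjd2a peaks without a partner (10.4%) had the centre of a Jmjd2c peak within 1 kb, and 20 of 383 such Jmjd2c peaks (5.22%) had that of a Jmjd2a peak.

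The dense X block appeared in both lists, with 242 of 293 Jmjd2c peaks (82.6%) and 227 of 409 Jmjd2a peaks (55.5%) shared. No excess of peak pairs at one distance was found inside the block, which argues only against long exact copies in the same orientation at equal spacing. At most 32 Jmjd2a peak pairs and 22 Jmjd2c pairs lay at one distance. The 95th percentiles were 38 and 27 when peaks were moved by up to 5 kb, and 33 and 24 when the gaps between peaks were shuffled. Both references leave runs of peaks near their places, so a regular spacing of runs without matching peaks was not tested. The same test on the Jmjd2a block with 2 exact copies of a 40-peak stretch added gave p = 0.001 (permutation). These copies lay at equal spacing and kept every peak. Short, diverged or inverted units were not simulated. In this block, copies at unequal spacing or with missing peaks were not simulated either. A candidate explanation that stays open is sequence held in many copies in the genome, whose reads pile up with any antibody. It cannot be told apart from binding of both proteins, because either predicts that most Jmjd2c block peaks meet a Jmjd2a peak, and no IgG peak list was analysed.

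The chromosome 5 block was called almost entirely in the Jmjd2c library. No excess of pairs at one distance was found, with at most 4 Jmjd2c pairs against a 95th percentile of 5 in sets of moved peaks. This cannot decide on repeated units, because copies were not simulated in a block of 30 peaks and so few peaks give little room for shorter units. Weaker detection in the Jmjd2a library cannot be told apart from a true difference: 0 of the 30 block peaks (0%) met a Jmjd2a peak, against 31.4% of score-matched Jmjd2c peaks from other autosomal regions (central 95% of 10000 draws 16.7 to 46.7), but the block was noticed for its lack of Jmjd2a peaks and its peaks are not independent. The other runs with a median score within 10 of the block's numbered 4, with 20 to 84.6% of peaks shared, too few to judge a whole run. Binding by Jmjd2c without Jmjd2a, a difference in copied sequence and a difference in the cells behind the 2 libraries also stay open, as untested.

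Outside the 6 blocks, peaks called in 1 library may be regions near the score floor of the peak caller. There, the median score of shared peaks exceeded that of one-library peaks by 42.05 in the Jmjd2a list and by 33.15 in the Jmjd2c list (permutation p = 1e-04 in each, the smallest 10000 resamples can give). Shared peaks had to be called in both lists, so their higher scores do not single out the score floor from other explanations. One-library peaks inside the blocks were not compared in this way, and no biological explanation for one-library peaks was tested.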
